A study of Mus musculus with 24 samples.

How the data were processed

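Gene expression was measured in subregions of the mouse suprachiasmatic nucleus, the paired hypothalamic nucleus that holds the master circadian clock. Per the labels' protocols, coronal brain cryosections were stained with haematoxylin and the ventral (core), central and dorsal SCN were isolated by laser microdissection. How the borders between the subregions were set is not given in the sources used here. RNA was purified with bacterial ribosomal RNA as a carrier, amplified and turned into biotin-labelled cDNA with Nugen Ovation kits, and this amplification and labelling was done in 2 batches, per the labels. One Affymetrix mouse expression array was used for each sample.

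The deposited table holds 1 log2 expression value for each of 45101 probe sets on each of 24 arrays, as processed by the authors. The submitters' processing notes name GCRMA 2.32.0, R 3.0.2 and MAS5, without saying what each was used for. GCRMA corrects the background of each probe with its base composition, normalizes between arrays and gives 1 value per probe set. The array medians fell into separate ranges that followed the labelled batches, from 3.52 to 3.62 in batch A and from 4.81 to 5.07 in batch B. Values of the 2 batches are therefore not on 1 scale, and the comparisons were made with the batch as a term or within a batch, with a fit without that term as an alternative. How the batches were normalized is not given in the sources used here.

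Probe sets were named with the platform annotation supplied with the table. Of the probe sets, 34945 had exactly 1 gene symbol, 932 had several and 9160 had none, and 64 were control probe sets. Entrez identifiers of 34754 of the probe sets with 1 symbol were found in a reference gene table of assembly GRCm38.p6, which changed 0 symbols. No genomic coordinates are given, because the values are not tied to a genome build in the sources used here. For the 9010 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene. Another probe set of the same gene went the other way for Egr3 in the ventral, central and averaged light effect, for Zfpm2, St8sia1 and Gca in the ventral, Prok2, Armc9 and Crem in the central and Nectin3 in the dorsal light effect, and for Mbp, Grik3, Dscaml1 and Fam184b in comparisons of regions. A gene was tested if its log2 value exceeded 4 on at least 4 arrays, which kept 13494 of 18193 genes and left out 4699. Control probe sets served only as quality measures.

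Samples were grouped by the region, treatment, replicate number and batch in their labels. This gave 6 groups of 4 arrays, and each group had 2 arrays in each batch. Replicates 1 and 2 belong to batch A, and replicates 3 and 4 to batch B. The labels do not say which arrays came from the same animal, and regions of 1 animal may lie on different arrays. The p-values therefore measure only the spread between these samples.

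Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated statistics, two-sided, Benjamini-Hochberg adjustment over the 13494 genes), and genes with an adjusted p under 0.05 are called changed, higher or lower. One fit with 6 group means and the batch term on all 24 arrays gave the light effect in each region (4 light against 4 sham arrays) and the differences between regions (8 against 8 arrays, both treatments). It had 17 residual and 4.7 prior degrees of freedom. The light effect averaged over the regions was fitted on 8 composite values, each the mean of the 3 regions for 1 treatment and replicate number, with 5 residual and 5.7 prior degrees of freedom. The interaction of light and region was tested with a moderated F statistic over the differences of the light effect between regions. Errors after ± are standard errors (SE) of log2 differences, unless SD is stated. The number of arrays limits the precision.

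The tests, the rule for named genes, the gene lists and the first set of alternatives were fixed before the data were examined. The rule takes, for each comparison, the 10 higher and the 10 lower genes with the largest log2 change among those that passed the test and went the same way in both batches, filled up to 5 by smallest p where fewer passed. It adds a panel of clock, light-response and SCN marker genes, and the 4 members with the smallest p of each gene list that is described. A panel gene, Nms, had no tested probe set.

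The 24 gene lists cover immediate early genes, later activity-dependent and CREB-regulated genes, feedback inhibitors of MAP kinase signalling, core clock genes, SCN core markers, SCN shell markers, other SCN-enriched genes, neuropeptides and their processing, neighbouring hypothalamic neurons, oligodendrocytes, astrocytes, microglia, endothelial and mural cells, ependymal cells and tanycytes, blood, neurons, chaperones, glutamate receptors, GABA receptors, G protein-coupled receptors and their regulators, voltage-gated channels, glucocorticoid and stress-response genes, ribosomal proteins and oxidative phosphorylation. Some genes stand on more than 1 list, for example Prok2 and Avp on the shell, SCN-enriched and neuropeptide lists. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists that had at least 3 tested genes. The blood list had 2 tested genes and was left out. Beside camera, an estimated correlation within each list and fry, which asks whether the genes of a list move on balance one way, were run. With the estimated correlation, 5 of 12 camera calls held for ventral light, 4 of 11 for central light, 0 of 5 for dorsal light and 1 of 13 for the averaged light effect. Of the calls between regions, 1 of 8 held for ventral against dorsal, 4 of 7 for ventral against central and 1 of 12 for central against dorsal. At an adjusted p under 0.05, fry called 3, 1, 2 and 1 lists for the 4 light comparisons and 10, 10 and 18 lists for the 3 region comparisons, in the same order.

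The fits were tested on simulated data built from the 13494 genes, with 200 genes changed, 100 of them by 2-fold and 100 by 4-fold. Noise was drawn independently for each gene and array, without an effect shared by arrays of 1 number, so the shares recovered hold for that setting. At 2-fold the test recovered 62% of the changed genes for the ventral, 64% for the central and 58% for the dorsal light effect, and 93% for the averaged effect, with 8 to 12 false calls. At 4-fold it recovered 95% to 100%. The interaction test recovered 36% at 2-fold and 86% at 4-fold. Between regions, 79% (ventral against dorsal), 86% (ventral against central) and 84% (central against dorsal) of the 2-fold changes were recovered. A simulated list of 40 genes shifted by 0.5 gave a camera p of 3.24e-31, and 4 of 200 unshifted lists fell under 0.05. As the simulated genes were independent, this does not show how camera behaves when genes of a list are correlated.

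Replicate numbers are shared by all groups, so it was checked whether they pair the arrays. In their deviations from the mean of their group and batch, arrays of different regions with the same treatment and number correlated at 0.185 to 0.623 in all 12 comparisons, so the numbers pair the regions. The labels do not say what ties arrays of 1 number together.

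The first set of alternatives held other batch and replicate terms, filters, probe set rules, normalizations, variance models, array weights, each batch alone, and each array left out in turn. Added after the data were seen were fits without array 4 of the dorsal light group, fits without that array and array 2 of the central light group, fits with the 3′ to 5′ difference of Gapdh as a covariate, and the averaged effect without all 3 arrays of 1 treatment and number.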

Results

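Gene expression was measured on 24 arrays, each hybridised with RNA from 1 subregion of the suprachiasmatic nucleus (SCN) of C57BL/6 mice. The SCN receives light input from the retina mainly in its ventral part, the core, where neurons make vasoactive intestinal peptide (Vip) and gastrin-releasing peptide (Grp), while neurons of the dorsal part, the shell, make vasopressin (Avp). Mice kept in constant dim red light received a light pulse of 30 min that advances the clock, or a sham treatment, and were killed 3.5 h later. The ventral, central and dorsal SCN gave 6 groups with 4 arrays each, 2 in each of the 2 amplification and labelling batches, A and B. The design asks which genes respond to the pulse in each subregion, whether the responses differ, and how the subregions differ from each other. The values are the authors' log2 expression values, and changes are given on the log2 scale with their standard error. Where a pair of numbers in parentheses carries no name, it gives the log2 change and the adjusted p.

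Arrays of 1 batch correlated at 0.938 to 0.987 in batch A and at 0.859 to 0.99 in batch B, while arrays of different batches correlated at 0.832 to 0.935. RNA quality was read from the 3′ and 5′ control probe sets of Gapdh, the transcript of a glycolytic enzyme, whose difference grows when cDNA is short. It lay between 2.02 and 3.28 in batch A and between 0.887 and 1.08 on 11 arrays of batch B. Array 4 of the dorsal light group had a difference of 5.41 and a median correlation of 0.872 with the other arrays of its batch, where the others had 0.976 to 0.983. It was kept, and counts without it are given beside each light effect.

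**Figure D1:**
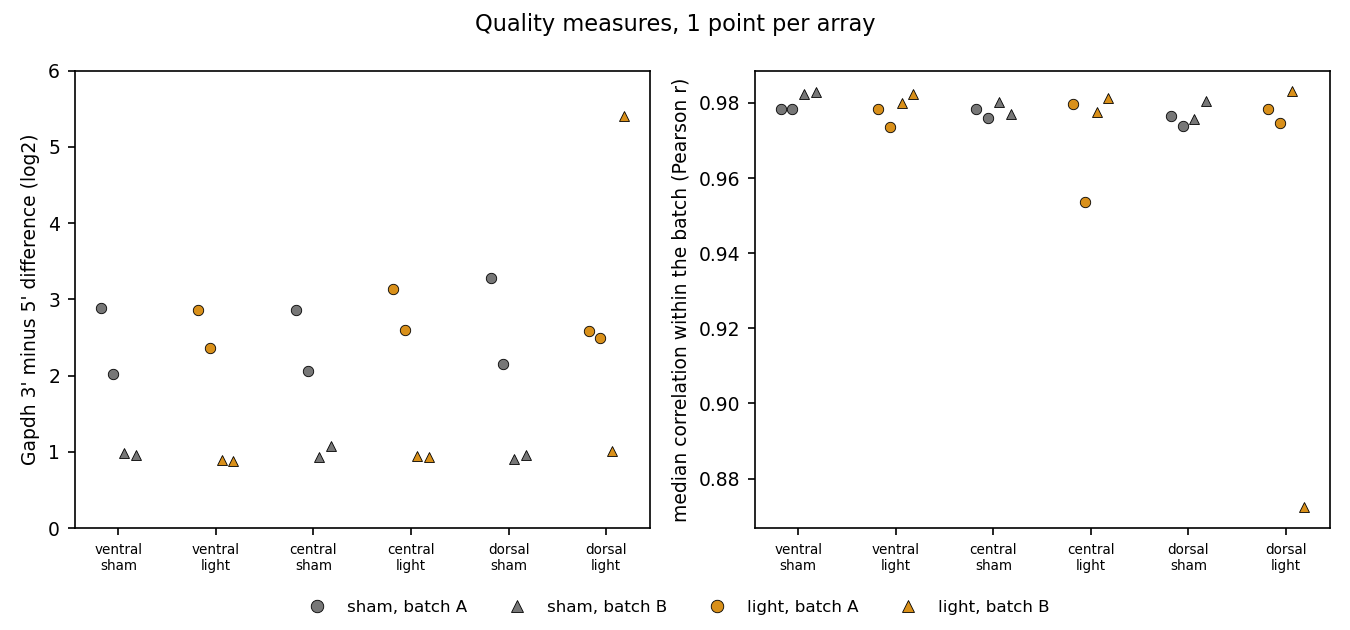
Difference between the 3′ and 5′ control probe sets of Gapdh (log2) and median Pearson correlation with the other arrays of the same batch, 1 point per array, by group and batch. Array 4 of the dorsal light group stands apart with a difference of 5.41 and a correlation of 0.872.

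In the ventral SCN the genes that the light pulse raised most included several that neuronal activity induces, with Per2 of the core clock and the peptide precursor gene Vgf also higher. Nptx1, a synaptic pentraxin, rose 10-fold (3.33 ± 0.235, adjusted p = 2.73e-08, 4 light against 4 sham arrays). The activity-induced transcription factor genes Egr3 (3.15 ± 0.514, adjusted p = 0.0024) and Fosb (2.40 ± 0.441, adjusted p = 0.00699) rose, both from sham means below the filter level of 4 in both batches (2.81 and 3.50 for Egr3, 3.32 and 3.91 for Fosb), so no fold is given for them. Crem, a cAMP-responsive transcription factor gene, rose 5.39-fold (2.43 ± 0.309, adjusted p = 0.000127). Per2, a repressor in the clock's feedback loop, rose 4.55-fold (2.19 ± 0.269, adjusted p = 8.31e-05). Vgf, the precursor of several secreted peptides, rose 5.29-fold (2.40 ± 0.278, adjusted p = 3.91e-05) and Prok2, a secreted output signal of the SCN, rose 6.12-fold (2.61 ± 0.557, adjusted p = 0.0235). Signal was low in batch A, with sham means below the filter level of 4 for Prok2 (3.22) and Crem (3.49), and 10 of the 31 named genes that passed had such a mean in their lower group.

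Of 13494 genes, 97 changed in the ventral SCN, 79 higher and 18 lower, and all 97 went the same way in both batches. Among the largest increases were also Socs3, a suppressor of cytokine signalling (2.98, adjusted p = 0.00386), Ddit4l, an inhibitor of mTOR signalling (2.43, adjusted p = 0.00133), Tinf2, a telomere-binding protein of the shelterin complex (2.36, adjusted p = 7.95e-08) and Hspa1b, an inducible Hsp70 chaperone (2.25, adjusted p = 0.00326). Sham means of Socs3 were 3.18 in batch A and 4.71 in batch B, below the mean array median of each batch. The largest decreases were in Ankrd63 (3.17-fold lower, -1.66, adjusted p = 0.0173), the chemokine gene Cxcl12 (-1.43, adjusted p = 0.0351), Sertm1 (-1.30, adjusted p = 0.00668), Pitpnc1, a phosphatidylinositol transfer protein (-1.27, adjusted p = 0.00217) and Abcc8, a subunit of ATP-sensitive potassium channels (-1.14, adjusted p = 0.0279). For Ankrd63 the light mean in batch A, 2.97, lay below the filter level, so its fold is imprecise. Pdgfc, a platelet-derived growth factor (-1.06, adjusted p = 0.00344), Gca (-1.04, adjusted p = 0.0375), the sialyltransferase gene St8sia1 (-0.97, adjusted p = 0.0173), Rasgrp1, an activator of Ras (-0.90, adjusted p = 0.00424), and Zfpm2 (-0.88, adjusted p = 0.0446) were lower too. Of the panel, Per1 (0.87, 0.639), Fos (0.64, 1), Egr1 (0.98, 0.105) and Arntl (0.77, 0.0977) did not pass the test. Nor did Dbp (-0.29, 0.999), Nr1d1 (-0.05, 1), Vip (0.00, 1), Avp (0.45, 1), Grp (-0.35, 0.888) and Rgs16 (0.46, 1) pass the test.

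Of 25 immediate early genes, 3 rose, Egr3, Fosb and Egr2 (1.38, 0.0174), and 7 rose when adjusted over the list alone. Immediate early genes as a list had camera adjusted p = 2.71e-08 and adjusted p = 4.69e-05 with an estimated correlation. Nr4a2 did not pass (adjusted p = 0.0702). Of 28 later activity-dependent and CREB-regulated genes, 4 rose, also adjusted over the list alone, namely Nptx1, Crem, Vgf and Pcsk1, a convertase that processes prohormones (1.90, adjusted p = 0.000775). Later activity-dependent genes as a list had camera adjusted p = 2.9e-13 and adjusted p = 2.64e-06 with an estimated correlation. Of 15 feedback inhibitors of MAP kinase signalling, Dusp4 (1.97, adjusted p = 0.0111) and Spred2 (1.09, adjusted p = 0.0131) rose, and 4 rose adjusted over the list alone. MAP kinase feedback inhibitors as a list had camera adjusted p = 1.76e-07 and adjusted p = 0.0367 with an estimated correlation. Spry4 (0.84, adjusted p = 0.397) and Spred3 (0.78, adjusted p = 0.428) did not pass. Of 8 shell markers, Prok2 and C1ql3, a synaptic C1q-like protein (1.18, adjusted p = 0.0135), rose, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000998 and adjusted p = 0.0367 with an estimated correlation), with Avpr1a at -0.90, adjusted p = 0.379 and Nmu at 0.45, adjusted p = 0.667. Glucocorticoid and stress-response genes had a median of 0.16, and 0 of 16 passed by either adjustment. Glucocorticoid and stress-response genes as a list had camera adjusted p = 0.00259 and adjusted p = 0.0367 with an estimated correlation. The smallest p values were those of Mt2 (0.79), Sgk1 (0.51) and Dusp1 (0.66).

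Per2 was the single core clock gene of 23 to rise, with 5 adjusted over the list alone. Core clock genes as a list had camera adjusted p = 0.00836 and adjusted p = 0.327 with an estimated correlation. Cry1 (0.60, adjusted p = 0.0868) and Rora (0.94, adjusted p = 0.145) did not pass. Of 27 neuropeptide and secretory granule genes, Prok2, Vgf, Penk, the enkephalin precursor (1.04, adjusted p = 0.0173), and Chga, a granule protein (0.76, adjusted p = 0.0418), rose, also adjusted over the list alone, while the list's median was -0.00. Neuropeptide genes as a list had camera adjusted p = 0.00973 and adjusted p = 0.102 with an estimated correlation. Of 20 SCN-enriched genes, 1 rose, and 3 rose and 2 fell adjusted over the list alone. SCN-enriched genes as a list had camera adjusted p = 0.02 and adjusted p = 0.178 with an estimated correlation. Lists of receptor and channel genes had negative medians. Among them, 0 of 18 glutamate receptor genes changed by either adjustment (median -0.29). Glutamate receptor genes as a list had camera adjusted p = 0.000978 and adjusted p = 0.148 with an estimated correlation. Of 10 GABA receptor genes Gabrb2 fell (-0.73, adjusted p = 0.0262), with 3 lower adjusted over the list alone (median -0.38). GABA receptor genes as a list had camera adjusted p = 0.00259 and adjusted p = 0.148 with an estimated correlation. Voltage-gated channels had a median of -0.20 with 0 of 28 changed by either adjustment (camera adjusted p = 0.0042 and adjusted p = 0.353 with an estimated correlation), and microglial genes one of 0.22 with 0 of 14 changed by either adjustment. Microglial genes as a list had camera adjusted p = 0.041 and adjusted p = 0.358 with an estimated correlation. Of 17 astrocyte genes Gfap, an intermediate filament, rose (1.28, adjusted p = 0.018), also adjusted over the list alone, while the list had a median of -0.13 (camera adjusted p = 0.475). Vim, another intermediate filament, rose (1.60, adjusted p = 0.00849) among 10 ependymal and tanycyte genes (camera adjusted p = 0.687).

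Within batch A alone 10 genes and within batch B alone 7 genes changed, each from 2 against 2 arrays per region. Without array 4 of the dorsal light group, 207 genes changed in the ventral SCN, with array weights 576, and in a fit of the ventral arrays alone 196. The 97 became 47 to 60 when light array 2 (47), 3 (60) or 4 (55) or sham array 1 (55), 2 (58), 3 (51) or 4 (53) was left out. Omission of 1 array ended some calls, and the highest adjusted p is given. This was 0.14 for Prok2, 0.21 for Cxcl12, 0.142 for Abcc8, 0.221 for Gca, 0.266 for Zfpm2, 0.0695 for Dusp4, 0.0895 for C1ql3, 0.244 for Chga and 0.169 for Gabrb2 without ventral light array 2. Without ventral light array 4 it was 0.0858 for Ankrd63, 0.0931 for Egr2 and 0.0712 for Spred2. It was 0.101 for St8sia1 without ventral sham array 1. Without ventral sham array 2 it was 0.0907 for Penk and 0.0907 for Gfap.

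In the central SCN the leading responses were again in activity-dependent genes. Nptx1 rose 8.35-fold (3.06 ± 0.235, adjusted p = 1.37e-07), Prok2 6.14-fold (2.62 ± 0.557, adjusted p = 0.0345), Vgf 4.06-fold (2.02 ± 0.278, adjusted p = 0.000806) and Crem 3.51-fold (1.81 ± 0.309, adjusted p = 0.00525), each from 4 light against 4 sham arrays. Per2 rose 2.8-fold (1.48 ± 0.269, adjusted p = 0.00949). Syt17, of the synaptotagmin family of vesicle proteins, fell and was 4.05-fold lower (-2.02 ± 0.414, adjusted p = 0.0256). Egr3 rose too (3.05 ± 0.514, adjusted p = 0.00525), from sham means below the filter level of 4 in both batches (2.76 and 3.51), so no fold is given. Sham means lay below that level for Prok2 (3.86) and Crem (3.82) in batch A, and 9 of the 24 named genes that passed had such a mean in their lower group.

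Of 13494 genes, 52 changed in the central SCN, 40 higher and 12 lower, all in the same direction in both batches. Pdzrn3 (2.25, adjusted p = 0.000371), Npnt, an extracellular matrix protein (1.92, adjusted p = 0.00525, from sham means of 3.61 and 3.97 in the 2 batches, both below the filter level), Sema3e, a guidance cue (1.91, adjusted p = 0.0497), Iqgap2 (1.89, adjusted p = 0.0113) and Gjb2, a connexin (1.74, adjusted p = 0.00462), were among the 10 largest increases. Iqgap2 had sham means of 2.91 in batch A and 4.21 in batch B, below the mean array median of each batch. The Wnt receptor genes Fzd5 (-1.11, 0.0113) and Fzd8 (-1.09, 0.00949) fell, as did Scn1a, a voltage-gated sodium channel (-1.03, 0.0167). Lower were also Pdgfa, a growth factor (-0.83, 0.00565), Ankrd35 (-1.04, 0.00462), Armc9 (-1.03, 0.0485), Pitpnc1 (-1.01, 0.022), Dsel (-0.93, 0.015) and Cc2d2a (-0.86, 0.0394). Of the panel, Per1 (0.71, 0.686), Fos (-0.53, 0.872), Egr1 (-0.04, 0.994) and Arntl (0.35, 0.73) did not pass the test. Nor did Dbp (-0.05, 0.993), Nr1d1 (-0.13, 0.961), Vip (0.26, 0.961), Avp (0.92, 0.446), Grp (-0.04, 0.994) and Rgs16 (0.71, 0.578) pass.

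Of 25 immediate early genes Egr3 rose, with 3 adjusted over the list alone (camera adjusted p = 0.00132 and adjusted p = 0.00857 with an estimated correlation, and camera adjusted p = 0.0732 without the 2 arrays that stand apart, dorsal light 4 and central light 2). Fosb (1.37, 0.308), Fosl2 (2.31, 0.32) and Nr4a1 (-1.48, 0.392) did not pass. Nptx1, Crem, Vgf and Pcsk1 (1.32, adjusted p = 0.0338) rose among the 28 later activity-dependent genes, also adjusted over the list alone. Later activity-dependent genes as a list had camera adjusted p = 2.1e-06 and adjusted p = 0.000315 with an estimated correlation. Of 27 neuropeptide genes Prok2, Vgf and Chga (0.88, adjusted p = 0.0193) rose, with 4 higher and 1 lower adjusted over the list alone. Neuropeptide genes as a list had camera adjusted p = 0.000882 and adjusted p = 0.0343 with an estimated correlation. Of 8 shell markers Prok2 and C1ql3 (1.19, adjusted p = 0.0172) rose, with 3 higher and 1 lower adjusted over the list alone. Shell markers as a list had camera adjusted p = 0.00132 and adjusted p = 0.0376 with an estimated correlation. For MAP kinase feedback inhibitors 0 of 15 passed and 3 rose adjusted over the list alone (camera adjusted p = 0.000753 and adjusted p = 0.169 with an estimated correlation), with Spred3 at 1.20, adjusted p = 0.0614 and Dusp4 at 1.31, adjusted p = 0.21.

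Per2 rose among 23 core clock genes, with 3 adjusted over the list alone, and the list's median of -0.01 became 0.10 when arrays were centred on their medians and 0.06 after quantile normalization. Core clock genes as a list had camera adjusted p = 0.0126 and adjusted p = 0.391 with an estimated correlation. Rorb (0.77, adjusted p = 0.0551) and Rora (0.96, adjusted p = 0.157) did not pass. SCN-enriched genes (camera adjusted p = 0.0102 and adjusted p = 0.169 with an estimated correlation) had 1 of 20 higher, and 3 higher and 1 lower adjusted over the list alone. Glutamate receptor genes had a median of -0.37 with 0 of 18 past the test, and 1 higher and 5 lower adjusted over the list alone. Glutamate receptor genes as a list had camera adjusted p = 0.0084 and adjusted p = 0.342 with an estimated correlation. Of 28 voltage-gated channels Scn1a fell, with 1 higher and 3 lower adjusted over the list alone. Voltage-gated channel genes as a list had camera adjusted p = 0.0259 and adjusted p = 0.445 with an estimated correlation. Chaperones (camera adjusted p = 0.0259 and adjusted p = 0.391 with an estimated correlation) and ribosomal proteins (camera adjusted p = 0.0259 and adjusted p = 0.406 with an estimated correlation) had 0 of 24 and 0 of 38 changed by either adjustment. Gfap (0.97, adjusted p = 0.155) and Vim (1.32, adjusted p = 0.0566) did not pass. Under median centring the median of all genes moved from -0.08 to 0.04.

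In batch A alone 8 genes and within batch B alone 5 genes changed in the central SCN, and without array 4 of the dorsal light group 164 changed. With array weights 204 changed, and in a fit of the central arrays alone 18. The 52 became 24 without sham array 2, 30 without sham array 3, 34 without sham array 4 and 34 without light array 3. Some calls ended when 1 array was left out, and the highest adjusted p is given. This was 0.161 for Prok2, 0.0661 for Fzd5, 0.0532 for Fzd8, 0.233 for Armc9, 0.175 for Cc2d2a and 0.104 for C1ql3 without central sham array 2. Without central sham array 1 it was 0.215 for Sema3e. It was 0.0674 for Iqgap2 without central light array 3. Without central light array 2 it was 0.117 for Syt17. It was 0.0703 for Scn1a without central sham array 4. Without central sham array 3 it was 0.112 for Pitpnc1, 0.0792 for Dsel, 0.0606 for Per2, 0.159 for Pcsk1 and 0.105 for Chga.

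In the dorsal SCN the light pulse raised Nptx1 and Egr3, as in the other regions, and lowered Ankrd63, Sertm1 and Dsel. Nptx1 rose 4.58-fold (2.20 ± 0.235, adjusted p = 6.42e-05) and Egr3 by 2.64 ± 0.514, adjusted p = 0.0287, each from 4 light against 4 sham arrays. Pdlim4, a cytoskeletal adaptor, rose 4.27-fold (2.10 ± 0.342, adjusted p = 0.00573), and Nectin3, a cell adhesion molecule, rose 2.75-fold (1.46 ± 0.215, adjusted p = 0.00231). Ankrd63 was 4.38-fold lower (-2.13 ± 0.341, adjusted p = 0.00494), Sertm1 3.23-fold lower (-1.69 ± 0.238, adjusted p = 0.00138) and Dsel 2.57-fold lower (-1.36 ± 0.179, adjusted p = 0.000954). In batch A, sham means of Egr3 (2.79) and Nectin3 (3.11) and the light mean of Ankrd63 (3.37) lay below the filter level of 4, as did a mean of the lower group in 8 of the 15 named genes that passed.

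Of 13494 genes, 24 changed in the dorsal SCN, 20 higher and 4 lower, all in the same direction in both batches. The split was 35 higher and 17 lower after quantile normalization and 21 higher and 11 lower after median centring. Klb, a co-receptor for fibroblast growth factors (2.07, 0.0199), Ntsr1, a neurotensin receptor (1.52, 0.0204, from sham means of 3.18 and 3.75 in the 2 batches, both below the filter level), Sema3a, a guidance cue (1.55, 0.0246), S100a10 (1.58, 0.0148), the transcription factor gene Creb3l1 (1.47, 0.0192), the galectin gene Lgals1 (1.45, 0.0114) and Gfap (1.33, 0.0319) rose, and Mycl, of the Myc family, fell (-0.97, 0.0287). Fzd5 (-0.95, 0.0682), Per2 (1.27, 0.0539), Prok2 (2.08, 0.195), Vgf (1.18, 0.0973), Crem (1.30, 0.105), Per1 (0.10, 0.924), Fos (-1.49, 0.264), Egr1 (0.09, 0.897), Arntl (0.65, 0.321), Dbp (0.35, 0.521), Nr1d1 (0.09, 0.866), Vip (1.07, 0.448), Avp (0.47, 0.589), Grp (0.76, 0.176) and Rgs16 (0.46, 0.566) did not pass.

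Of 28 later activity-dependent genes Nptx1 rose, with 4 adjusted over the list alone. This list had camera adjusted p = 0.0408 and adjusted p = 0.11 with an estimated correlation. Ependymal and tanycyte genes had a median of 0.39, with 0 of 10 past the test and 1 adjusted over the list alone. The list had camera adjusted p = 0.00361 and adjusted p = 0.124 with an estimated correlation. On array 4 of the dorsal light group these markers had a median of 0.89 above array 3, and without array 4 the list had a median of 0.25 (camera adjusted p = 0.00451). Vim (1.25, adjusted p = 0.113) and Hdc (0.96, adjusted p = 0.45) had the smallest p. Core markers (camera adjusted p = 0.0474 and adjusted p = 0.269 with an estimated correlation), SCN-enriched genes (camera adjusted p = 0.0408 and adjusted p = 0.269 with an estimated correlation) and neuronal genes (camera adjusted p = 0.0408 and adjusted p = 0.269 with an estimated correlation) had 0 members past the test, and 1 higher, 2 higher with 1 lower, and 2 lower adjusted over the list alone. Under median centring the list tests of later activity-dependent genes (adjusted p = 0.0583), core markers (0.0874), SCN-enriched genes (0.0932) and neuronal genes (0.0583) no longer passed. Array 4 of the dorsal light group, with its Gapdh difference of 5.41, belongs to this comparison: without it 41 genes changed, and the lists of core clock genes (camera adjusted p from 0.0553 to 0.000219), shell markers (0.0553 to 0.000368) and MAP kinase feedback inhibitors (0.427 to 0.000368) came to pass.

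Within batch A alone 2 genes and within batch B alone 0 genes changed in the dorsal SCN, the latter with 1276 at an unadjusted p under 0.05 in limma. A fit of the dorsal arrays alone ended every call, with 0 genes and 428 at an unadjusted p under 0.05 in limma, while array weights gave 353 genes. The 24 became 12 without sham array 1, 12 without sham array 2 and 13 without sham array 3. Omission of 1 array ended some calls, and the highest adjusted p is given. This was 0.168 for Egr3, 0.155 for Sema3a, 0.155 for Mycl and 0.168 for Gfap without dorsal sham array 3. Without dorsal sham array 1 it was 0.0709 for Klb, 0.0709 for Ntsr1, 0.0939 for Creb3l1 and 0.0676 for Lgals1. It was 0.0726 for S100a10 without dorsal sham array 2.

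Averaged over the 3 regions, the light pulse raised several activity-dependent genes, Per2 and the intermediate filament genes Vim and Gfap. Nptx1 rose 7.27-fold (2.86 ± 0.178, adjusted p = 0.000103), Per2 3.13-fold (1.65 ± 0.137, adjusted p = 0.00101), Vgf 3.65-fold (1.87 ± 0.219, adjusted p = 0.00546) and Crem 3.6-fold (1.85 ± 0.202, adjusted p = 0.00456), from 4 light against 4 sham composites. Egr3 rose too (2.94 ± 0.404, adjusted p = 0.0113), with no fold given as its sham means of 3.15, 3.14 and 3.55 in the 3 regions lay below the filter level of 4. Vim rose 2.62-fold (1.39 ± 0.157, adjusted p = 0.00456) and Gfap 2.29-fold (1.19 ± 0.193, adjusted p = 0.0253). Ankrd63 was 3.4-fold lower (-1.77 ± 0.246, adjusted p = 0.0116).

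In all, 55 genes changed in the average, 48 higher and 7 lower, each in the same direction in both batches. Prok2 (2.44, 0.024), Socs3 (1.97, 0.00866), Pdlim4 (1.91, 0.00456), Sema3e (1.78, 0.0223), Pdzrn3 (1.69, 0.00738) and Pcsk1 (1.35, 0.00546) rose. The other 6 lower genes were Sertm1 (-1.33, 0.0132), Pi16 (-1.16, 0.032), Pitpnc1 (-0.96, 0.0236), Dsel (-0.89, 0.0369), Fzd5 (-0.84, 0.0422) and Ankrd35 (-0.76, 0.0436). Per1 (0.56, 0.418), Fos (-0.46, 0.759), Egr1 (0.34, 0.545), Arntl (0.59, 0.25), Dbp (0.00, 0.999), Nr1d1 (-0.03, 0.984), Vip (0.45, 0.606), Avp (0.61, 0.336), Grp (0.12, 0.895) and Rgs16 (0.54, 0.412) did not pass. The later activity-dependent genes were the list whose call held with an estimated correlation (camera adjusted p = 1.81e-07 and adjusted p = 0.0294 with an estimated correlation), with Nptx1, Crem, Vgf and Pcsk1 higher among 28, also adjusted over the list alone. Immediate early genes had 1 of 25 higher, and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000135 and adjusted p = 0.0621 with an estimated correlation), MAP kinase feedback inhibitors 0 of 15, and 5 higher adjusted over the list alone (camera adjusted p = 0.000368 and adjusted p = 0.231 with an estimated correlation), and shell markers 1 of 8, and 4 higher and 1 lower adjusted over the list alone. Shell markers as a list had camera adjusted p = 0.000834 and adjusted p = 0.0862 with an estimated correlation. The remaining list calls, of core clock, SCN-enriched, neuropeptide, microglial, ependymal, glutamate receptor, GABA receptor, G protein-coupled receptor and glucocorticoid genes, had camera adjusted p from 0.0019 to 0.0476 and adjusted p from 0.0862 to 0.325 with an estimated correlation.

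In batch A alone 3 genes and within batch B alone 4 genes changed in the average, and with array weights 476. The 55 became 34 without ventral light array 4, 83 without dorsal light array 3 and 106 without dorsal light array 4. Without all 3 arrays of light number 3 they became 34, and without those of sham number 1, 2, 3 or 4 they became 35, 21, 20 or 13. Calls of some genes ended when 1 array or the 3 arrays of a treatment and number were left out, and the highest adjusted p is given. This was 0.0842 for Egr3, 0.0662 for Socs3, 0.105 for Sema3e, 0.085 for Ankrd63 and 0.158 for Pi16 without the 3 sham arrays with number 4. Without the 3 sham arrays with number 2 it was 0.138 for Prok2, 0.0855 for Sertm1, 0.14 for Pitpnc1, 0.218 for Dsel, 0.264 for Fzd5 and 0.145 for Gfap. It was 0.235 for Ankrd35 without the 3 sham arrays with number 3.

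**Figure D2:**
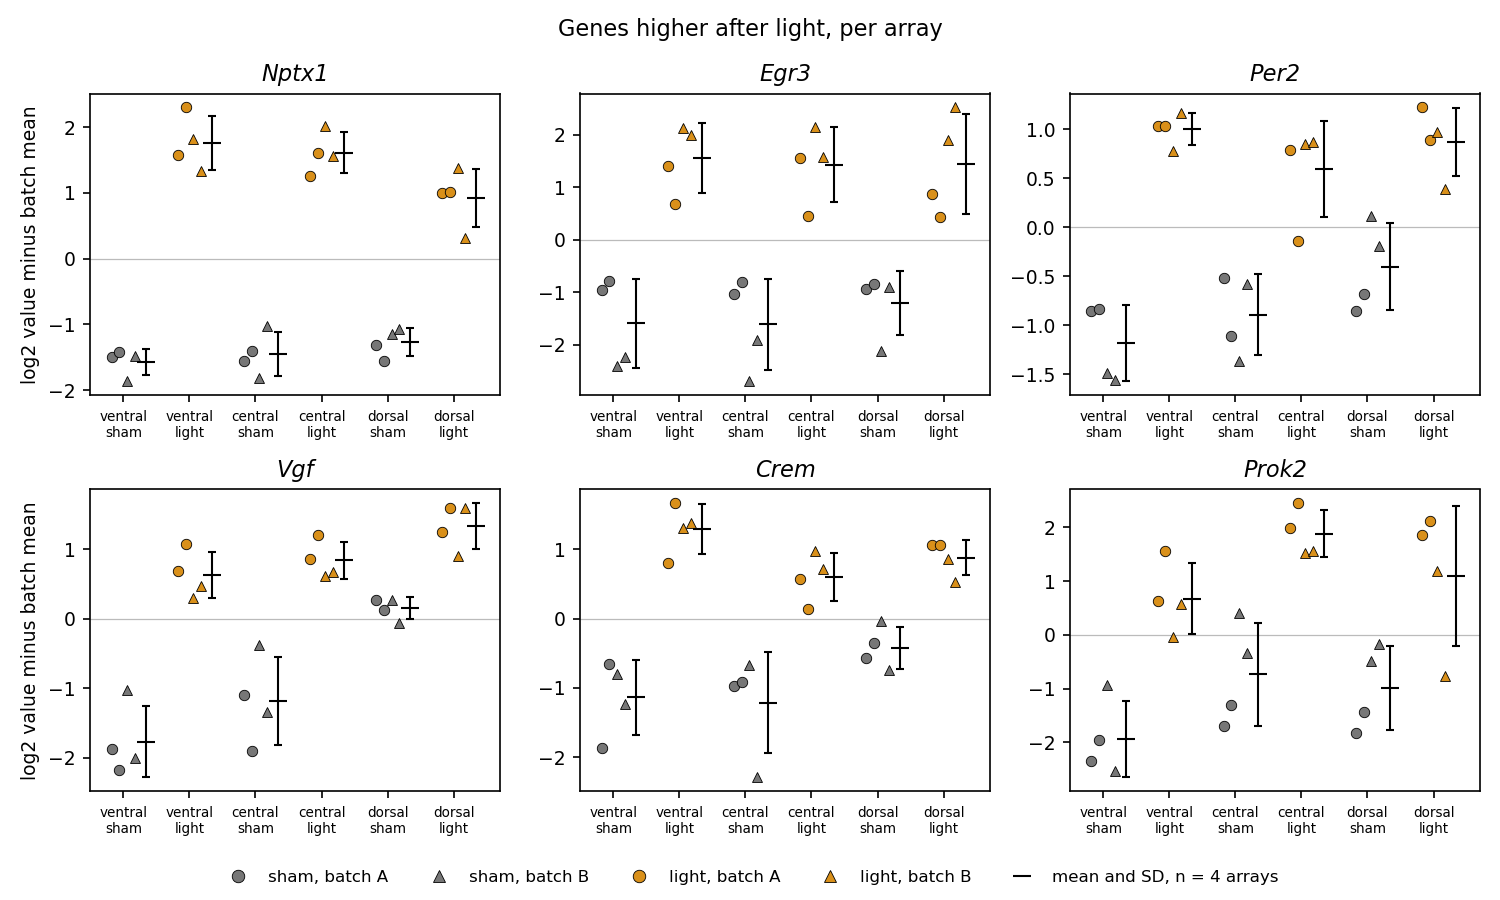
Expression of Nptx1, Egr3, Per2, Vgf, Crem and Prok2 on each array (log2 minus the mean of the batch) in sham and light groups of the ventral, central and dorsal SCN, with circles for batch A, triangles for batch B, and bars for mean ± SD of 4 arrays. Nptx1 was higher after light by 3.33 in the ventral, 3.06 in the central and 2.20 in the dorsal SCN.

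Whether the response differed between regions was tested directly, and 1 gene passed, Tinf2 (interaction adjusted p = 0.0362). At an unadjusted p under 0.05 in limma there were 276 genes, fewer than the 675 expected by chance. The fit took no account of the pairing of regions by replicate number, so this test may be too strict. Tinf2 rose in the ventral (2.36 ± 0.182) and central SCN (1.18 ± 0.182, adjusted p = 0.00236), with a dorsal value of 0.58 (adjusted p = 0.328). Its light effect was larger in the ventral than in the dorsal SCN by 1.78 ± 0.258, adjusted p = 0.00935, while its difference between ventral and central SCN, 1.17 ± 0.258, adjusted p = 1, and that between central and dorsal SCN, 0.60 ± 0.258, adjusted p = 0.984, did not pass. Nptx1, Fosb, Vgf, Crem and Per2 had larger estimates in the ventral than in the dorsal SCN, without passing the test: the difference was 1.13 ± 0.333, adjusted p = 0.937 for Nptx1, 2.36 ± 0.623, adjusted p = 0.937 for Fosb, 1.22 ± 0.393, adjusted p = 0.937 for Vgf, 1.13 ± 0.437, adjusted p = 0.937 for Crem and 0.91 ± 0.38, adjusted p = 0.937 for Per2. Egr3 (0.51 ± 0.727, adjusted p = 0.94) and Prok2 (0.53 ± 0.788, adjusted p = 0.94) differed less than their errors. A gene that passed in 1 region and not in another is thus not shown to differ between them, apart from Tinf2 between ventral and dorsal SCN. This single interaction call also ended in other fits, with 0 genes under the replicate block in place of the batch (470 at an unadjusted p under 0.05 in limma), in batch A alone (377), in batch B alone (208), over all probe sets (586), with the mean over probe sets (256) and with a trend and robust variance (249). Leaving out single arrays gave 0 to 2 calls (2 without central light array 2), and the count was 0 without any one of 16 arrays, namely ventral light arrays 1, 2 and 4, ventral sham arrays 1 to 4, central light array 1, central sham arrays 1, 2 and 4, dorsal light arrays 2 and 3 and dorsal sham arrays 2, 3 and 4.

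Between the ventral and the dorsal SCN, irrespective of the treatment, the neuropeptide genes Sst and Vip had the largest decrease and increase. Vip was 10.8-fold higher in the ventral SCN (3.44 ± 0.298, adjusted p = 9.97e-08, 8 against 8 arrays) and Grp 3-fold higher (1.59 ± 0.141, adjusted p = 1.56e-07). Sst, the somatostatin precursor, was 38.4-fold lower (-5.26 ± 0.423, adjusted p = 4.02e-08), Penk 4.25-fold lower (-2.09 ± 0.15, adjusted p = 1.17e-08) and Avp 2.7-fold lower (-1.43 ± 0.249, adjusted p = 0.00074) in the ventral SCN. Of 8 markers of neighbouring hypothalamic neurons, Oxt, the oxytocin precursor, was lower too (-2.04, adjusted p = 0.00853) and 0 were higher (camera adjusted p = 0.237 for the list). Whether dorsal samples held neighbouring tissue was not tested. Dsg2, a desmosomal cadherin, was 10.5-fold higher (3.39 ± 0.175, adjusted p = 4.5e-11).

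Of 13494 genes, 622 differed, 355 higher and 267 lower in the ventral SCN. After quantile normalization 372 were higher and 392 lower. Higher were also Dsc2, another desmosomal cadherin (2.47), Zfp703 (2.19), the neuropeptide Y receptor gene Npy6r (2.15), Ermn, a myelin-associated protein (2.15), the growth factor gene Hbegf (2.06), Sfrp2, a Wnt antagonist (1.86), Stk32a (1.86) and Slc6a3, the dopamine transporter (1.84). Lower were the receptor genes Adgrg2 (-2.36), Gpr101 (-2.33), Qrfpr (-2.12) and Glra2, a glycine receptor subunit (-2.29), Tac2, a tachykinin precursor (-2.14), Fstl5 (-2.23), Asb4 (-2.12) and the homeobox gene Dlx1 (-2.09). Of the other panel genes, Calb2 (1.26, 0.000123), Cck (1.04, 0.00252), Mbp (1.01, 0.0204) and Gfap (0.98, 0.00191) were higher and Calb1 lower (-0.39, 0.0198), and Prok2 did not pass (-0.69, 0.436).

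Of 11 core markers 6 were higher and 3 lower, and adjusted over the list alone 6 higher and 4 lower. Core markers as a list had camera adjusted p = 0.0516 and adjusted p = 0.276 with an estimated correlation. Of 27 neuropeptide genes 4 were higher and 7 lower, and 4 and 9 adjusted over the list alone. Neuropeptide genes as a list had camera adjusted p = 0.01 and adjusted p = 0.132 with an estimated correlation. Oligodendrocyte genes were higher in the ventral SCN, 9 of 16 and 12 adjusted over the list alone (median 1.00, camera adjusted p = 4.14e-17 and adjusted p = 0.00971 with an estimated correlation), among them the myelin genes Mog (1.78), Mobp (1.61) and Mal (1.45). Of 17 astrocyte genes 3 were higher, and 5 adjusted over the list alone (camera adjusted p = 9.03e-06 and adjusted p = 0.149 with an estimated correlation), led by Aqp4, a water channel (0.78, adjusted p = 0.000126). Of 18 neuronal genes Syt1, a calcium sensor of vesicle release (-2.04, adjusted p = 2.26e-10), and the neurofilament gene Nefl (-1.21, adjusted p = 0.00127) were lower, with 3 lower adjusted over the list alone. Neuronal genes as a list had camera adjusted p = 0.00171 and adjusted p = 0.132 with an estimated correlation. Of 10 ependymal and tanycyte genes Ccdc153 (-1.59), Dynlrb2 (-1.01) and Cfap126 (-0.75) were lower and 0 higher (camera adjusted p = 0.0517). Of 18 glutamate receptor genes 1 was higher and 5 lower, and 2 and 6 adjusted over the list alone (camera adjusted p = 0.01 and adjusted p = 0.276 with an estimated correlation), with Gria3 at -1.08, Grin3a at -0.90 and Grik3 at -1.24. Of 10 GABA receptor genes Gabrb2 (-0.99), Gabra4 (-0.66) and Gabra3 (-0.46) were lower, also adjusted over the list alone (camera adjusted p = 0.01 and adjusted p = 0.256 with an estimated correlation).

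Within batch A alone 153 and within batch B alone 124 genes differed between ventral and dorsal SCN. The labels do not say which arrays share an animal. With treatment and replicate number as a random block 934 genes differed, and with a fixed block microglial genes (median -0.20) came to pass as a list (camera adjusted p = 0.0476). Omission of 1 array ended some calls, and the highest adjusted p is given. This was 0.0542 for Calb1 without dorsal sham array 3. Without ventral sham array 1 it was 0.055 for Mbp and 0.0943 for Gabra3.

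Between the ventral and the central SCN, myelin genes were among those with the largest differences and were higher in the ventral SCN. Mog was 9.27-fold higher (3.21 ± 0.173, adjusted p = 1.15e-10, 8 against 8 arrays) and Mbp, myelin basic protein, 6.23-fold higher (2.64 ± 0.253, adjusted p = 5.37e-07). Cck, the cholecystokinin precursor, was 4.28-fold higher (2.10 ± 0.205, adjusted p = 6.97e-07), and Trh, the thyrotropin-releasing hormone precursor, was higher too (1.87 ± 0.266, adjusted p = 7.38e-05). Penk was 2.75-fold lower (-1.46 ± 0.15, adjusted p = 1.06e-06) and Grp was lower (-0.89 ± 0.141, adjusted p = 0.000251). Vip (0.55, adjusted p = 0.495) and Avp (0.44, adjusted p = 0.539) did not differ past the test.

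Of 13494 genes, 702 differed, 588 higher and 114 lower in the ventral SCN. After median centring 405 were higher and 200 lower, and the median of all genes moved from 0.05 to -0.07. Among the 10 most increased were also Tmem88b (3.19), Mobp (3.18), Mal (2.97), Ermn (2.80), Cldn11 (2.54), Gsn (2.43), Plekhh1 (2.38) and Ugt8a (2.37). Lower were the receptor genes Adgrg2 (-2.45), Ghsr (-1.61) and Gpr83 (-1.56), the tachykinin gene Tac2 (-1.57), the cerebellin gene Cbln4 (-1.81), Mctp2 (-2.07), Shisa6 (-1.85), Cthrc1 (-1.67), Nkd1 (-1.47) and Csgalnact1 (-1.47). Prok2 (-1.21, adjusted p = 0.0898), Calb1 (0.03, adjusted p = 0.992), Calb2 (0.55, adjusted p = 0.115) and Gfap (0.52, adjusted p = 0.137) did not pass.

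Oligodendrocyte genes were higher in 15 of 16 cases, and 16 adjusted over the list alone (median 1.82). The list had camera adjusted p = 3.43e-49 and adjusted p = 2.13e-05 with an estimated correlation. Astrocyte genes were higher in 11 of 17 cases, and 16 adjusted over the list alone (median 0.76, camera adjusted p = 2.92e-17 and adjusted p = 0.00442 with an estimated correlation), with S100b (1.08), Ntsr2 (0.90), Gjb6 (0.87) and Aqp4 (0.64) at the smallest p. Of 15 endothelial and mural genes 6 were higher, and 9 adjusted over the list alone (median 0.54, camera adjusted p = 2.48e-09 and adjusted p = 0.0474 with an estimated correlation), among them the transporter genes Slco1a4 (1.21) and Abcb1a (1.19) and the tight junction gene Cldn5 (1.10). Of 14 microglial genes Tyrobp (0.65) and Fcer1g (0.51) were higher, and 4 adjusted over the list alone. The list had camera adjusted p = 0.00129 and adjusted p = 0.204 with an estimated correlation. Of 10 ependymal and tanycyte genes Enkur (0.54) and Hdc (0.94) were higher, and 4 adjusted over the list alone. This list had camera adjusted p = 0.0234 and adjusted p = 0.22 with an estimated correlation. Of 8 markers of neighbouring neurons Trh, Pmch (0.959, adjusted p = 0.00333) and Otp (1.575, adjusted p = 0.0325) were higher and 0 lower (camera adjusted p = 0.139). Of 18 glutamate receptor genes Gria3 was higher (0.69) and Grin3a (-1.25), Grin2d (-0.56) and Grm7 (-0.59) lower, and 2 and 4 adjusted over the list alone (camera adjusted p = 0.0234 and adjusted p = 0.381 with an estimated correlation).

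In batch A alone 199 and within batch B alone 176 genes differed between ventral and central SCN, and without array 4 of the dorsal light group, which enters through the shared spread, 1092 differed. Some calls ended when 1 array was left out, and the highest adjusted p is given. This was 0.0994 for Enkur without central sham array 3. Without central sham array 4 it was 0.121 for Hdc. It was 0.076 for Grin2d without ventral sham array 4. Without ventral light array 2 it was 0.0795 for Grm7. The labels do not say which arrays share an animal.

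Between the central and the dorsal SCN, Vip was 7.39-fold (2.89 ± 0.298, adjusted p = 1.05e-06) and Grp 5.55-fold higher (2.47 ± 0.141, adjusted p = 1.93e-10) in the central SCN, from 8 against 8 arrays. Sst was 26.2-fold lower (-4.71 ± 0.423, adjusted p = 1.44e-07), Avp 3.65-fold lower (-1.87 ± 0.249, adjusted p = 2.97e-05), and Oxt, the oxytocin precursor, was lower too (-2.29 ± 0.457, adjusted p = 0.00232). Ccn3, a matrix-associated signalling protein, was among the largest increases (2.61 ± 0.149, adjusted p = 1.93e-10). Mbp was 3.1-fold lower in the central SCN (-1.64 ± 0.253, adjusted p = 0.000181).

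Of 13494 genes, 959 differed, 265 higher and 694 lower in the central SCN. After median centring 501 were higher and 485 lower, and the median of all genes moved from -0.05 to 0.06. Higher were also Cthrc1 (2.39), Dsg2 (2.34), Npy6r (2.33), Nectin3 (2.29), Fam184b (2.20), Thsd7b (2.02) and Insyn2a (1.91). Lower were Fstl5 (-2.97), Gpr101 (-2.76), Asb4 (-2.54), the calcitonin receptor gene Calcr (-2.48), Sytl4 (-2.20), Rasd2 (-2.14), Dscaml1 (-2.13) and A930009L07Rik (-1.98). Of the other panel genes Calb2 was higher (0.72, adjusted p = 0.0187), Calb1 (-0.43, adjusted p = 0.00792) and Cck (-1.05, adjusted p = 0.00184) were lower, and Prok2 (0.52, adjusted p = 0.504) and Gfap (0.45, adjusted p = 0.168) did not pass.

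Of 11 core markers 5 were higher and 5 lower, and 5 and 6 adjusted over the list alone, with a median of -0.43 and a mean of 0.34. Core markers as a list had camera adjusted p = 0.121 and adjusted p = 0.322 with an estimated correlation. SCN-enriched genes had 2 of 20 higher and 2 lower, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.0147 and adjusted p = 0.131 with an estimated correlation, and camera adjusted p = 0.0899 without dorsal light array 4 and central light array 2), with the homeobox gene Lhx1 higher (0.98, adjusted p = 0.00015). Of 27 neuropeptide genes 2 were higher and 11 lower, and 2 and 13 adjusted over the list alone. The list had camera adjusted p = 0.0084 and adjusted p = 0.0805 with an estimated correlation. Markers of neighbouring hypothalamic neurons had 3 of 8 lower, also adjusted over the list alone, namely Oxt, Trh (-1.92, adjusted p = 4.64e-05) and Otp (-1.87, adjusted p = 0.0077). This list had camera adjusted p = 0.00713 and adjusted p = 0.0805 with an estimated correlation. Of 18 neuronal genes 5 were lower, and 6 adjusted over the list alone (camera adjusted p = 0.00716 and adjusted p = 0.121 with an estimated correlation), including Syt1 (-1.86) and Nefl (-1.67).

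Oligodendrocyte genes were lower in the central than in the dorsal SCN, while the calls of the other glial and vascular lists were lost with an estimated correlation. Of 16 oligodendrocyte genes 11 were lower, and 15 adjusted over the list alone (median -0.97, camera adjusted p = 4.55e-15 and adjusted p = 0.0175 with an estimated correlation), with Cldn11 (-1.40), Mog (-1.44), Olig1 (-1.03) and Mobp (-1.58) at the smallest p. Of 14 microglial genes 6 were lower, and 9 adjusted over the list alone (median -0.55). The list had camera adjusted p = 7.19e-06 and adjusted p = 0.0767 with an estimated correlation, with Fcer1g at -0.69. Of 15 endothelial and mural genes 6 were lower, and 9 adjusted over the list alone (median -0.47, camera adjusted p = 1.06e-06 and adjusted p = 0.0805 with an estimated correlation), among them Slco1a4 (-1.48). Of 10 ependymal and tanycyte genes Dynlrb2 (-1.52), Ccdc153 (-1.97) and Cfap126 (-1.11), which belong to motile cilia, were lower, and 6 adjusted over the list alone. This list had camera adjusted p = 0.000208 and adjusted p = 0.0764 with an estimated correlation. Of 17 astrocyte genes 6 were lower, and 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 0.00228 and adjusted p = 0.226 with an estimated correlation).

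Within batch A alone 185 and within batch B alone 214 genes differed between central and dorsal SCN. The labels do not say which arrays share an animal. With treatment and replicate number as a fixed block 1541 genes differed, and with a random block 1568.

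**Figure D3:**
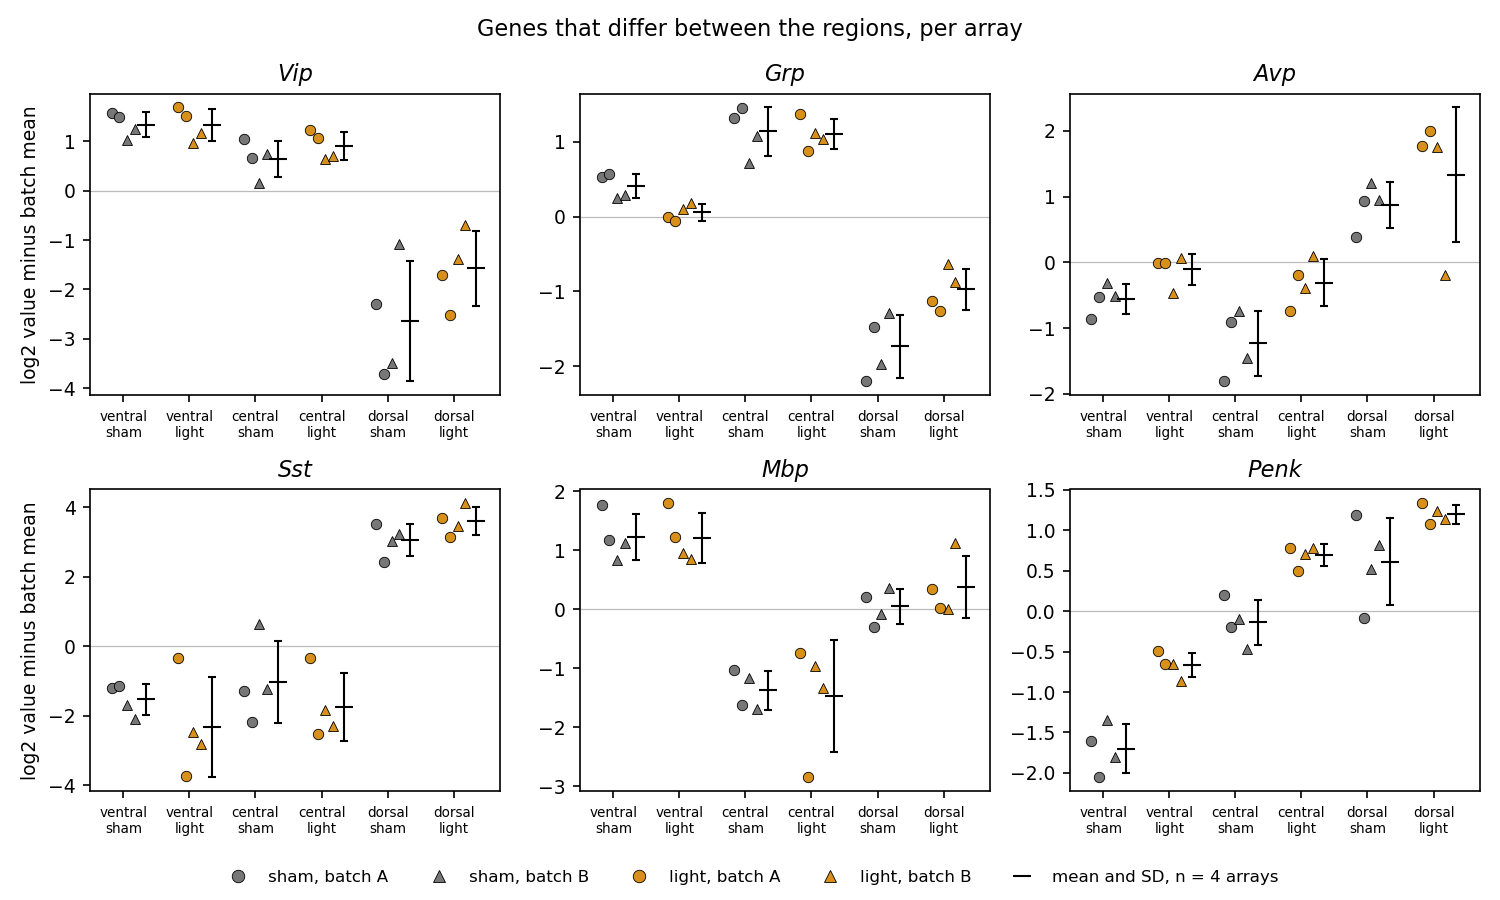
Expression of Vip, Grp, Avp, Sst, Mbp and Penk on each array (log2 minus the mean of the batch) in the ventral, central and dorsal SCN, with grey for sham, orange for light, circles for batch A, triangles for batch B, and bars for mean ± SD of 4 arrays. Sst was lower by 38.4-fold in the ventral and 26.2-fold in the central than in the dorsal SCN.

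**Figure D4:**
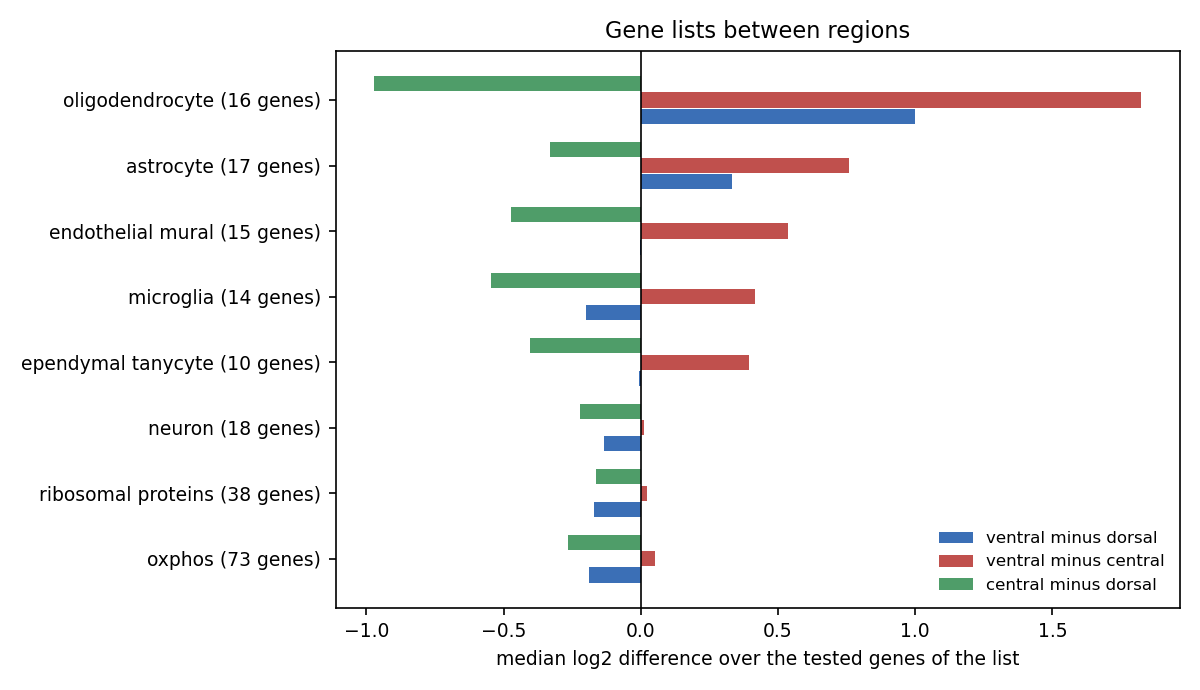
Median log2 difference of 8 gene lists in the 3 comparisons between regions, 1 bar per list and comparison. The oligodendrocyte list has the medians 1.82 (ventral minus central), 1.00 (ventral minus dorsal) and -0.97 (central minus dorsal).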

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

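All tests of explanations in this part were chosen after the result was seen, except the test for degraded RNA, which was chosen before its result was seen.

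Array 4 of the dorsal light group stands apart: its 3′ minus 5′ log2 difference was 5.41 for Gapdh and 4.143 for Actb, its median correlation within the batch was 0.8723, and 1206 genes deviated more than 4-fold from array 3 of the group and batch, 471 higher and 735 lower. A wrong region label is argued against, because over 1889 genes that differ between regions the array correlated best with the dorsal mean, by 0.61 over the next region (0.28, against -0.34 for ventral and -0.33 for central). Degraded RNA stays open: 0 of 3 further control transcripts also had the highest difference. This does not decide, as their 5′ signals on other batch B arrays left little room to fall (3.13 to 5.46, 0 above 6). 18S rRNA was lower at both ends (5′ below the range of 4.24 to 5.46 and 3′ at 6.55 against 7.20 to 8.36). Another cell type also stays open. Markers of neighbouring hypothalamic neurons (8 genes, median 1.40 above array 3, from -1.1 to 2.2) lay at the 99.9th percentile of expression-matched random lists. Ependymal and tanycyte markers (10 genes, median 0.89, from -2.36 to 2.05) followed, then microglia (88), endothelial cells (65.8), oligodendrocytes (62.5) and astrocytes (26.7). This used array 3 alone, so added neighbouring tissue is not shown. In batch B the dorsal light mean lay below sham for Oxt (-3.60), Otp (-1.75), Trh (-1.60) and Pmch (-0.34). A first version measured the list median against the spread of single genes and was set aside. Its bound of 2.11 would have argued against another cell type. No biological explanation was tested.

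Gfap and Vim rose in the average (1.19 and 1.39), and Gfap also stood out on array 4 of the dorsal light group, at 10.14. More astrocytes in the light samples are argued against by the other 16 astrocyte markers, whose median light effect was -0.22 (from -0.52 to 0.17, 3 positive), and RNA quality by a fit with the Gapdh difference as a covariate, in which both genes passed (Gfap 1.00 ± 0.15 and Vim 1.32 ± 0.16, highest adjusted p = 0.0278). Tissue of the ventricle wall stays open as a source. In the average, 9 other ependymal and tanycyte markers (median 0.13, from -0.16 to 0.32) lay below 0.69, 0.5 times the effect on Vim. This bound replaced a first one, a median of at most 0.1, after the values were seen, so it does not decide. In the dorsal SCN their median was 0.29 and the highest lay at 0.96, above the bound of 0.63. As a hypothesis, a glial response of the reactive type may contribute: of 24 reactive astrocyte genes without Gfap and Vim, 12 were tested, 9 were positive and the list shifted up (median 0.15, camera p = 9.09e-05, and p = 0.00913 with an estimated correlation), but 0 of them passed limma's test, with 4 at an unadjusted p under 0.05.

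Glial and vascular marker lists had lower medians in the central region than in both others, and the difference held with an estimated correlation on both sides for oligodendrocytes. A lower share of the main cell type elsewhere is argued against as the only source of the oligodendrocyte difference between ventral and central. The median of that list was 1.82 (quartiles 1.38 and 2.68). This was at least 1.06 more than the astrocyte (0.76), microglial (0.42), endothelial (0.54) and ependymal (0.40) lists. For these other lists a lower share stays open, because the test measured only the excess of the oligodendrocyte list over them. An offset between array medians is argued against for the oligodendrocyte list between ventral and central, whose median was 1.70 after centring. Centring moved the median of all genes there from 0.05 to -0.07. The smaller differences of the other lists, and those between central and dorsal, were not tested in this way. White matter of the optic chiasm, which lies below the SCN, could be a source of the higher oligodendrocyte values in the ventral samples. That list was higher in ventral than in dorsal samples in both batches, by at least 0.82, with the abundant Mbp (mean 10.48) higher by 1.00 and Cnp (10.61) by 0.52. Another probe set of Mbp went the other way, and the call of Mbp ended without ventral sham array 1. The difference between ventral and dorsal was known when this test was chosen, so it does not decide for the chiasm. Chiasm in the ventral samples leaves the differences between central and dorsal samples unexplained, for oligodendrocytes (median -0.97) as for astrocyte, vascular and microglial genes. A true difference in glia between the regions stays open as untested.

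Single arrays lay far from the rest of their group, among 120 groups of which chance gives about 1 in 20, or 6, and 10 were seen, 4 of them given above for array 4 of the dorsal light group (Gapdh, Actb, the correlation and Gfap). The other 6 were the Gapdh difference of 3.279 on dorsal sham array 1, the median correlation of 0.9535 on central light array 2, Per2 at 5.264 on central light array 2, Egr3 at 3.692 on dorsal sham array 3, Avp at 8.094 on dorsal light array 4 and Avp at 7.829 on ventral light array 3. The light effect on Tinf2 differed between regions (interaction adjusted p = 0.0362), though this call ended in several other fits and array omissions, as given above. Of 5916 probe sets without exactly 1 gene symbol, not used in the comparisons by gene, 11 passed for the ventral light effect (10 higher, 1 lower), 6 for the averaged light effect (5 higher, 1 lower) and 82 between ventral and dorsal SCN (47 higher, 35 lower). For central light 11 passed (8 higher, 3 lower) and for dorsal light 4 (3 higher, 1 lower). Between ventral and central SCN 71 passed (57 higher, 14 lower), and between central and dorsal SCN 132 (48 higher, 84 lower).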

How the results depend on the processing

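Fits without dorsal light array 4, without that array and central light array 2, with the Gapdh 3′ minus 5′ difference as a covariate, and without all 3 arrays of a treatment and number were chosen after seeing the data. Counts are of genes past limma's test, in the order ventral light, central light, dorsal light, averaged light, interaction, ventral against dorsal, ventral against central, central against dorsal, which were 97, 52, 24, 55, 1, 622, 702 and 959. Where a count moved by over 1.5 times, the cause was not tested, though each single batch holds fewer samples. Without the batch term the counts were 0, 0, 0, 0, 0, 4, 9 and 7 (28, 21, 23, 13 and 1 at an unadjusted p under 0.05 for the zeros). Array weights gave 576, 204, 353, 476, 2, 1374, 1390 and 1762. Batch A alone gave 10, 8, 2, 3, 0, 153, 199 and 185 (377 unadjusted for the 0), and batch B alone 7, 5, 0, 4, 0, 124, 176 and 214 (1276 and 208 unadjusted for the zeros). Quantile normalization gave 94 for central light, 52 for dorsal light and 2 for the interaction, and median centring 86 for central light, 87 for averaged light and 2 for the interaction. The arrays of a region alone gave 196 for ventral, 18 for central and 0 for dorsal light (428 unadjusted). The interaction count was 0 over all probe sets (586 of 30983 unadjusted), with the mean over probe sets (256 of 12920) and with a trend and robust variance (249). Averaging the regional effects over all arrays gave 549, and 172 with the random replicate block. Sham arrays alone gave 438 for ventral against central and 628 for central against dorsal, and light arrays alone 83, 86 and 86 for the region comparisons.

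Light and sham arrays with the same number correlated at 0.096 to 0.4 over 6 comparisons. As 1 of the 6 lay below 0.1, the numbers were not taken to pair light and sham arrays, which leaves a weaker tie between them possible. With the replicate block in place of the batch, central light had 98, dorsal light 40 and averaged light 113 genes, and the interaction 0 (470 unadjusted). The random replicate block gave 934 for ventral against dorsal, 1568 for central against dorsal and 2 for the interaction, and the fixed replicate block 1541 for central against dorsal. Apart from the microglial list between ventral and dorsal, the fixed block changed no list call and moved no other region count over all genes by over 1.5 times.

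Without dorsal light array 4, the counts were 207 for ventral, 164 for central, 41 for dorsal and 106 for averaged light, and 1092 for ventral against central. Without it and central light array 2 they were 307, 128, 54, 206, and 2 for the interaction, and 1078 for ventral against central. With the Gapdh covariate they were 212, 175 and 50 for the regional light effects and 1080 for ventral against central. Leaving out 1 array or composite of the groups compared gave 47 to 81 for ventral, 24 to 45 for central, 12 to 41 for dorsal and 13 to 106 for averaged light, 0 to 2 for the interaction, 488 to 727 for ventral against dorsal, 549 to 686 for ventral against central and 714 to 1185 for central against dorsal. Of the named gene values, 300 were followed through the alternatives and 225 of these passed: over their 7446 alternative values, 6426 passed with the same sign, 1020 no longer passed and 0 reversed. Of 2201 alternative values of the genes that did not pass, 147 passed. Low signal limits the light effects, since Egr3, for example, had sham means of 3.15, 3.14 and 3.55 in the ventral, central and dorsal SCN, below the filter level of 4, and a batch mean of the lower group lay below it for 10 of 31, 9 of 24 and 8 of 15 named genes that passed. As the batches are not on 1 scale, the lower group was also set against the mean array median of each batch, and lay below it for 7, 4 and 5 of these genes in batch A and 4, 3 and 2 in batch B.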

Other observations

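The test of recurrence across regions in this part was fixed before its result was seen, as were the tests of other splits, except the count of splits that keep the batches balanced, which was chosen after.

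Some genes of energy metabolism and protein synthesis were lower in the central than in the dorsal SCN. Of 73 oxidative phosphorylation genes 10 were lower, and 29 adjusted over the list alone (median -0.26, camera adjusted p = 2.24e-09 and adjusted p = 0.121 with an estimated correlation), with Cox6a2, a cytochrome c oxidase subunit (-1.16, adjusted p = 0.000271), Atp5b, an ATP synthase subunit (-0.38, adjusted p = 0.0125), and the complex I genes Ndufa12 (-0.36, adjusted p = 0.0157) and Ndufb5 (-0.52, adjusted p = 0.0169) at the smallest p. Of 38 ribosomal protein genes 3 were lower, and 11 adjusted over the list alone (camera adjusted p = 0.000358 and adjusted p = 0.121 with an estimated correlation), with Rpl22 at -0.43, adjusted p = 0.00458. With treatment and replicate number as a fixed block, 23 oxidative phosphorylation and 7 ribosomal protein genes were lower. Oligodendrocyte (median -0.97), microglial (-0.55) and endothelial and mural genes (-0.47) had negative medians in this comparison too. Between ventral and dorsal SCN, 1 of 73 oxidative phosphorylation genes was lower, also adjusted over the list alone and 8 with the fixed block (median -0.19, camera adjusted p = 3.42e-10 and adjusted p = 0.169 with an estimated correlation), and 1 of 38 ribosomal protein genes, also adjusted over the list alone (median -0.17, camera adjusted p = 3.79e-06 and adjusted p = 0.132 with an estimated correlation). Glucocorticoid and stress-response genes were higher in the ventral than in the central SCN, 4 of 16, 8 adjusted over the list alone and 7 with the fixed block (median 0.41, camera adjusted p = 1.27e-05 and adjusted p = 0.00442 with an estimated correlation), among them Pdk4, a kinase that restrains pyruvate oxidation (0.97, adjusted p = 7.01e-06), and the metallothionein genes Mt2 (0.87, adjusted p = 0.00362) and Mt1 (0.75, adjusted p = 0.0165). Higher there as well were oligodendrocyte (median 1.82), astrocyte (0.76) and endothelial and mural genes (0.54). In the central against the dorsal SCN 5 of the glucocorticoid and stress-response genes were lower, and 1 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0112 and adjusted p = 0.0805 with an estimated correlation).

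Channel and receptor genes went both ways between central and dorsal SCN. Of 28 voltage-gated channels 5 were higher and 6 lower, and 5 and 9 adjusted over the list alone (camera adjusted p = 0.427 and adjusted p = 0.782 with an estimated correlation): the potassium channel genes Kcnh1 (1.18, adjusted p = 1.56e-06) and Kcna5 (1.49, adjusted p = 1.6e-05) were higher, and Scn1a (-1.47, adjusted p = 4.17e-07) and Kcnk2 (-0.99, adjusted p = 0.000528) lower. Of 21 genes of G protein-coupled receptors and their regulators 3 were higher and 7 lower, and 4 and 7 adjusted over the list alone (camera adjusted p = 0.337 and adjusted p = 0.522 with an estimated correlation), with the regulators of G protein signalling Rgs10 (-1.45, adjusted p = 4.47e-07) and Rgs8 (-0.93, adjusted p = 0.000561) lower and Npy5r, a neuropeptide Y receptor (1.31, adjusted p = 0.000756), higher. Mtnr1a, a melatonin receptor, was higher in the ventral than in the dorsal SCN (1.29, adjusted p = 3.24e-05). The clock gene Rorb was lower in the ventral (-0.80, adjusted p = 0.000197) and in the central (-0.66, adjusted p = 0.0013) than in the dorsal SCN.

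A light response shared by the regions may underlie the separate lists of changed genes, as a hypothesis. Of the 100 genes with the smallest p for light in ventral batch A, 74 had the same sign of the light effect in dorsal batch B, against 58 and 61 for the other splits of those 4 arrays. In central batch B 91 had the same sign, against 62 and 57. The test used different regions and replicates for choosing and for counting, but the labels do not say whether arrays share animals. As 4 arrays allow no further splits of this kind, the real one can often lead by chance. Array 4 of the dorsal light group, which stands apart, is among the dorsal arrays used.

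Other splits of the arrays tested each count against chance, and in each case 1 split, the real one, gave as many genes. Chance could be excluded for the differences between regions. The ventral light effect had 97 genes against at most 0 in the other splits of 35, the central one 52 against 0 and the dorsal one 24 against 2. The averaged effect had 55 against 34 over 34 splits, and 1 further split, which follows the batch, could not be fitted. Of the splits for each light effect, 18 keep 2 arrays of each group in each batch, which are too few for a share under 0.05, and the highest other count among them was 0, 0, 1 and 34 for the ventral, central, dorsal and averaged effect. The interaction had 1 gene against 0 over 100 drawn splits, but this single call ended without any one of 16 arrays and in each batch alone, so chance is not taken as excluded for it. Ventral against dorsal had 622 against 97, ventral against central 702 against 65 and central against dorsal 959 against 2, over 100 splits each, and against 145, 174 and 332 over 100 splits each that part every pair of same-numbered arrays.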
